A study of Rattus norvegicus with 6 samples.

How the data were processed

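RNA levels were measured in the thoracic aorta of 24-week-old rats of the strains SHR and WKY, on 3 Affymetrix Rat Gene 2.0 ST arrays per strain, 6 arrays in all. Strain and replicate number were taken from the sample titles. The deposited table holds log2 values per probe set, made by the authors with RMA in Affymetrix Expression Console 1.2.1, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarizes the probes of a probe set by median polish. The log2 base follows from the definition of RMA and from the range of the values. Values were not centred per gene. The level of summarization, the annotation version and the genome build are not given in the sources used here. The table gives no detection p, so a dim probe set has a level but no call of presence. The medians of the arrays, from 2.29 to 2.52, were not identical, and the deposited values were used as they stand. Sequencing depth does not apply to arrays, and the number of arrays limits the precision. No per-sample column of another sample was present in the table.

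The table holds 28879 probe sets, of which 334 have at least 1 copy with identical values on all 6 arrays. In the platform annotation 18511 probe sets have 1 gene symbol, 575 have several and 9793 are not listed, and only those with 1 symbol were named. Entrez identifiers matched 18394 of them to the RefSeq gene table of assembly GRCr8, which gave current symbols and the class of the gene. The platform symbol was kept for the other 117. GRCr8 served for names, classes and the order of genes along chromosomes, and no position is printed, since the build behind the probe sets is not stated. Only 41 probe sets belong to genes that the table classes as long non-coding. The class of probe sets without a gene name is unknown here, and many long non-coding transcripts of the array may be among them.

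Probe sets were tested if their mean over the 6 arrays was at or above the 25th percentile, a log2 level of 1.17, which kept 21659 and left out 7220. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust estimation), with the strain as the only term. Differences are SHR minus WKY, tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets. An adjusted p under 0.05 is called passing. A gene with several tested probe sets, as 235 genes had, was represented by the one with the highest mean, which left 15281 genes. Levels are means ± SD over 3 arrays, and SE is that of the fitted difference. In data simulated for this comparison on 21659 probe sets, the fit recovered 26.2% of changes of 1 log2 unit, 88% of changes of 2 and 97% of changes of 3, and 4.38% of its calls were false. The simulated noise was independent between probe sets, equal on all arrays and drawn from the fit's own variance model. A false share near the threshold of 0.05 was therefore built in. The real arrays were unequal, with fitted array weights from 0.22 (WKY replicate 3) to 2.05 (SHR replicate 2), so these shares are not estimates for the real arrays.

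Gene lists were fixed before the data were examined: 18 programmes of vascular biology, 1 list of genes reported in earlier genetic work on SHR, and 11 lists of markers of cell types that a dissected aorta can hold. Each was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the first 19 lists and over the 11 marker lists separately. The same lists were tested by camera with an estimated correlation and by fry, which asks whether the genes of a list move one way and does not compare them with other genes. The members of a list are counted as adjusted over all probe sets and as adjusted over the list alone. Sympathetic neuron and pancreatic acinar cell lists were added after related genes had been seen on single arrays, and hold none of those genes.

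The named genes follow a rule fixed at the same time. It takes the 12 largest increases and 12 largest decreases among passing protein-coding genes whose strains do not overlap, leaving out provisional symbols and olfactory or vomeronasal receptors, and 5 of each among non-coding RNAs. Where fewer than 5 pass in a direction it takes the 5 with the smallest unadjusted p, said not to pass. From each list it takes the 4 measured members with the smallest unadjusted p, of which the text prints those that matter most, and every measured gene of the SHR genetics list. The receptor gene Olr1 encodes the lectin-like receptor of oxidised low-density lipoprotein and was not treated as olfactory. Genes named outside this rule are said to have been chosen after their values were seen.

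The alternatives, changed 1 at a time, were a block for the replicate number, no filter on dim probe sets, the 50th percentile as the filter, a further quantile normalization, median centring, an intensity trend with a robust prior, array weights, leaving out each array in turn, other thresholds, the mean of a gene's probe sets and the other set tests. Leaving out both SHR replicate 1 and WKY replicate 3, the white adipocyte mean as a covariate and counting identical probe sets once were chosen after seeing the data. A planned test of coding neighbours of changed non-coding RNAs, with both its alternatives, was not run, since it needed at least 10 changed non-coding RNAs and 0 passed. Correlations of list means over the 6 arrays were tested over all 720 pairings. Figures were drawn with matplotlib 3.10.9.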

Results

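RNA levels were compared between the aortae of spontaneously hypertensive rats (SHR), an inbred strain that develops high blood pressure, and of Wistar-Kyoto rats (WKY), the related strain with normal pressure that is commonly used as its control. The rats were 24 weeks old and untreated. Each strain had 3 microarrays, on which groups of short probes, called probe sets, report the level of a transcript. The labels do not state that each array held a different animal, so the p-values measure only the spread between these samples, which may be technical. The 6 arrays did not group by strain: the mean correlation across probe sets was 0.980 for the 6 pairs of arrays within a strain and 0.979 for the 9 pairs between strains. WKY replicate 3 had the narrowest spread of values, with an SD over probe sets of 2.12 against 2.22 to 2.27 on the other 5 arrays, and its correlations with them were between 0.961 and 0.975. Against the mean of the other 5 arrays its values lay higher among dim probe sets, by a median of up to 0.21, and lower among bright ones, by a median down to -0.28, when probe sets were binned by level.

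The comparison of the strains asked which coding and long non-coding RNAs differ in the aorta of the hypertensive rats. The largest measured increase was in Il1rl2, a receptor of the interleukin family, which lay at a log2 level of 6.76 ± 0.17 (SD, n = 3) in SHR and 2.33 ± 0.18 in WKY. The measured levels differed by 4.43 ± 0.17 on the log2 scale (SE; limma adjusted p = 0.000267). Olr1, the scavenger receptor that takes up oxidised low-density lipoprotein, was higher in SHR, at 4.98 ± 0.21 against 1.63 ± 0.12 (limma adjusted p = 0.000916). No detection call exists, and the array medians were 2.29 to 2.52. The WKY levels of both genes, like those of Trpc4 (2.55), Clec2gl1 and Fam110c, are therefore not shown to lie above background. Nor is the SHR level of Mettl24. The differences given for these genes are between measured levels and are not estimates of a fold in RNA. The same limit holds for any named gene with a strain mean near or under 2.52, such as Cacna1d (2.53 in WKY). Trpc4, a calcium-permeable cation channel, was higher by 3.04 ± 0.27 (SE) on the log2 scale and Thbs4, a thrombospondin of the extracellular matrix, by 2.01 ± 0.19, both at a limma adjusted p of 0.0297. Mettl24, a methyltransferase-like gene, was lower in SHR, at 2.26 ± 0.47 against 5.34 ± 0.57 in WKY (limma adjusted p = 0.0395).

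In all, 15 of 21659 tested probe sets passed, 13 higher and 2 lower in SHR. They represent 13 named genes, all protein-coding, and 2 probe sets without a gene name. On every one of these genes the 3 SHR arrays lay on the same side of the 3 WKY arrays. Among all tested probe sets 12.1% were separated in this way, where chance gives 10%. The other increases were Clec2gl1, a C-type lectin gene (measured log2 difference 2.46), Fam110c (1.96), Vsnl1, a neuronal calcium sensor (1.88), Rtel1, a helicase that maintains telomeres (1.54), Ptpa, an activator of a protein phosphatase (1.40), and Bcat1, the cytosolic aminotransferase of branched-chain amino acids (1.35). The other decrease was Sh3bgr (-2.25). Probe sets 17812648 and 17707346, which have no gene name here, were higher in SHR by 2.09 and 1.67. At an unadjusted p under 0.05 there were 1202 probe sets, 651 higher and 551 lower, where chance alone gives 1083.

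**Figure D1:**
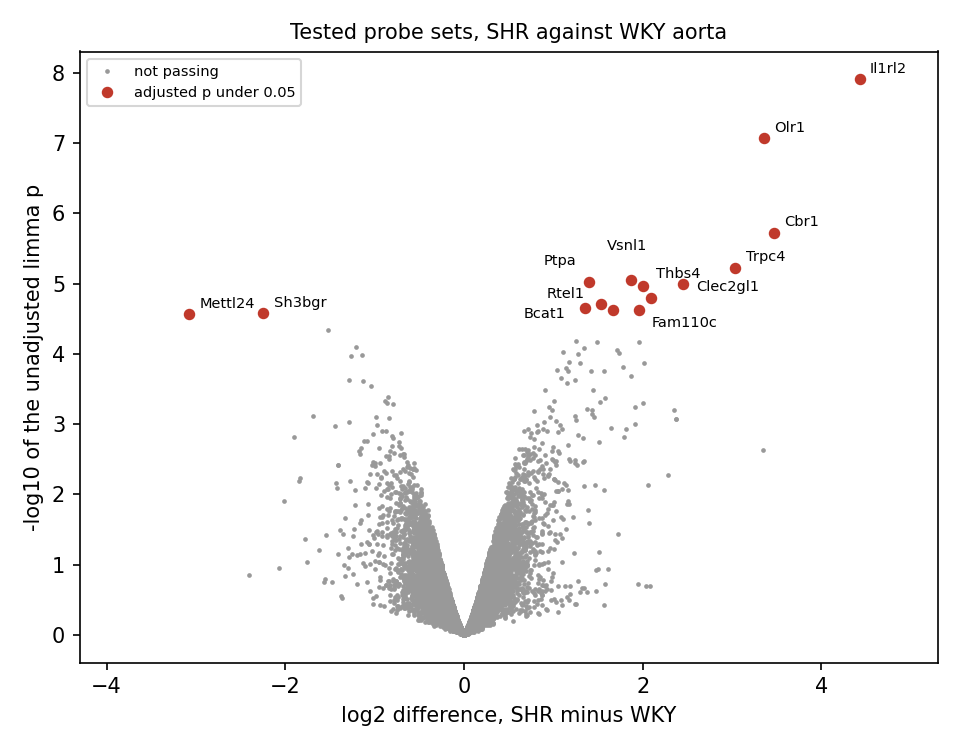
Each point is 1 of 21659 tested probe sets, with the log2 difference SHR minus WKY on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red points are the 15 probe sets that passed, of which the 13 with a gene name are labelled. Of the 15, 13 lie to the right and 2 to the left. The positions of Il1rl2, Olr1, Trpc4, Clec2gl1, Fam110c and Mettl24 rest on measured levels not shown to lie above background in 1 of the strains.

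**Figure D2:**
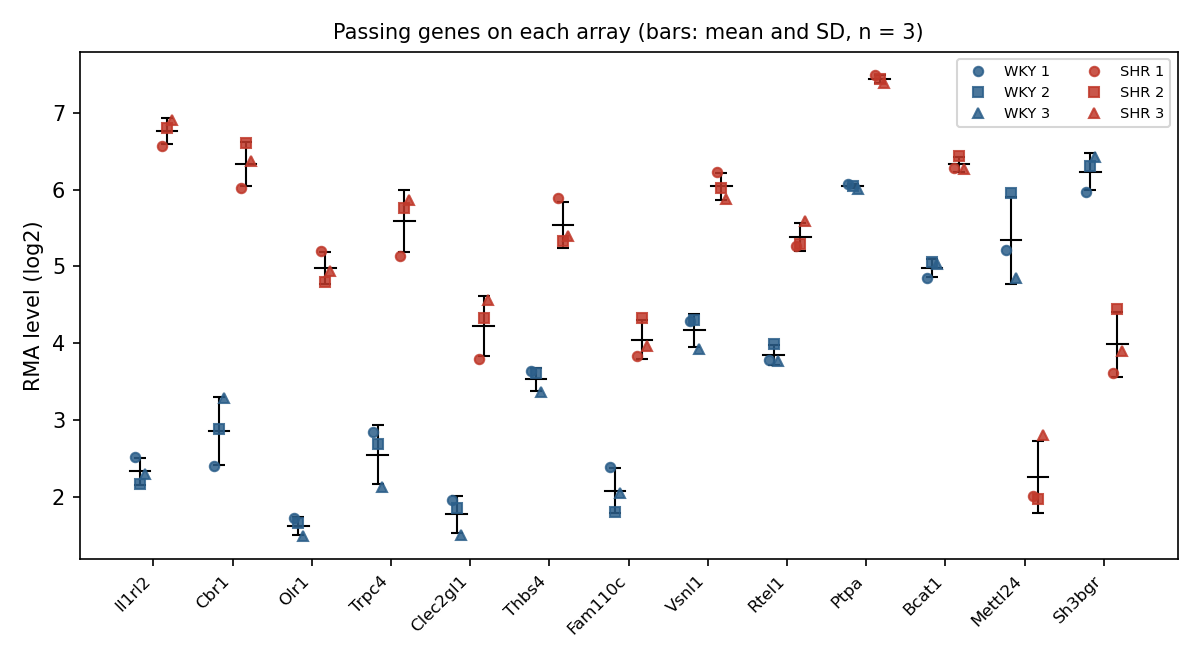
The RMA level (log2) of the 13 passing genes is shown on each array, blue for WKY and red for SHR, with the replicate given by the shape of the point and bars for the mean and SD (n = 3). The strains do not overlap for any of these genes, and Il1rl2 lies at 6.76 in SHR and 2.33 in WKY on average.

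Cbr1, a carbonyl reductase, rested on 1 of its 3 probe sets. Probe set 17664759, the brightest on average, was higher in SHR by 3.47 ± 0.26 (SE; limma adjusted p = 0.0136). Probe sets 17664770 and 17664766 of the same gene differed by -0.06 and -0.22, with limma adjusted p of 0.968 and 0.923. With the mean of the 3 probe sets the difference of Cbr1 was 1.06 and did not pass. Cbr1 was the only passing gene with more than 1 tested probe set. Each other passing gene, Il1rl2 and Olr1 included, rests on 1 probe set, so a sequence difference between the strains under its probes is not excluded.

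The count of passing probe sets fell whichever array was left out, with fewer arrays in each fit. It was 5 without SHR replicate 1, 2 without SHR replicate 2, 3 without SHR replicate 3, 3 without WKY replicate 1, 2 without WKY replicate 2 and 3 without WKY replicate 3. The differences themselves moved less: over the 6 fits Il1rl2 ranged from 4.35 to 4.52, Ptpa from 1.37 to 1.42 and Mettl24 from -3.35 to -2.77. Il1rl2 and Olr1 passed in each of these 6 fits, with limma adjusted p up to 0.0102 and 0.0166. Cbr1 did not pass without SHR replicate 2 (0.127), SHR replicate 3 (0.106) or WKY replicate 2 (0.149). Trpc4 and Clec2gl1 passed only without SHR replicate 1 (0.0211 each), and the other 8 genes passed in none of the 6 fits, with limma adjusted p from 0.0673 to 0.292. Without SHR replicate 3, Chi3l1, a gene outside the naming rule, passed as well. Without both SHR replicate 1 and WKY replicate 3, a setting chosen after seeing the data, 115 probe sets passed, 39 higher and 76 lower, and all 13 genes were among them. Of the 127 genes that the naming rule takes although they did not pass, 65 had a difference that moved by over 1.5 times or changed sign without 1 of the arrays.

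Among genes lower in SHR only Sh3bgr and Mettl24 passed. The next by unadjusted p did not: Pi15, a secreted inhibitor of proteases, differed by -1.52 (limma adjusted p = 0.0611), Fndc5, the precursor of irisin, by -1.21 (0.0842) and Agtr1b, a subtype of the angiotensin II receptor, by -1.14 (0.0848).

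No long non-coding RNA passed. Of 33 such genes tested, 3 had an unadjusted p under 0.05, where chance gives 1.65, and the smallest limma adjusted p was 0.795 over all probe sets and 0.479 when adjusted over this class alone. Those 3 were Ly49si1l1, at 2.39 ± 0.13 in SHR and 1.91 ± 0.20 in WKY, 2810025M15Rikl, at 3.56 ± 0.11 and 3.13 ± 0.26, and the imprinted Meg3, at 1.46 ± 0.07 and 1.83 ± 0.12. Further members with the smallest p were Prkcel1, C7h12orf54 and LOC100911266 on the higher side and RGD1563049, LOC690120, CB741658 and Tom1l3 on the lower, with differences from -0.42 to 0.16. The differences of 2810025M15Rikl (0.28 without WKY replicate 3), Prkcel1, C7h12orf54, LOC100911266, LOC690120, CB741658 and Tom1l3 moved by over 1.5 times without 1 of the arrays. Passing genes were 13 of 14821 protein-coding and 0 of 33 long non-coding ones. Fisher's exact test gave a two-sided p of 1, but at the coding share only 0.0289 passing long non-coding genes would be expected, so the number tested was too small to show a lower share. Of 188 probe sets for small RNAs 0 passed and 7 had an unadjusted p under 0.05, where chance gives 9.4. The 5654 tested probe sets without a gene name held both unnamed passing ones, and their class is unknown here.

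Of the 19 programme and candidate lists, 6 passed camera with a preset correlation, 2 higher and 4 lower in SHR. With an estimated correlation 0 of the 19 passed (0 at an unadjusted p under 0.05), and by fry 0 passed (3 at an unadjusted p under 0.05). Those 3 were fibrillar matrix (fry unadjusted p = 0.0149), cell cycle (0.0210) and basement membrane (0.0475), of which only cell cycle is among the 6. For mitochondrial respiration the unadjusted p was 0.302 by fry. In camera with an estimated correlation it was 0.299, against 0.0759 for cell cycle. Among the 6 lists the estimated correlation ran from 0.063 (cell cycle) to 0.551 (mitochondrial respiration), above the preset 0.01. The preset treats the genes of a list as nearly independent, so its p-values are too small where they move together. List p-values below are at the preset unless another test is named. The cell cycle list was higher in SHR, with a mean log2 difference of 0.22 over 21 measured genes and an adjusted p of 0.0104 (adjusted p = 0.664 with an estimated correlation). The mean level of the list was 2.83 ± 0.10 in SHR and 2.61 ± 0.02 in WKY. That is near the array medians of 2.29 to 2.52, so the list mean is not shown to lie above background. None of its members passed in limma over all probe sets (4 had an unadjusted p under 0.05), and 3 were higher when adjusted over the list alone. The proliferation marker Mki67 lay at 3.52 ± 0.44 in SHR and 2.54 ± 0.07 in WKY, and Rrm2, which makes deoxyribonucleotides, at 2.07 ± 0.05 and 1.42 ± 0.13, both below every array median. The log2 difference of Ccnd1, a cyclin of the early cell cycle, was 0.66 ± 0.15 (SE). The mitotic factor Tpx2 lay at 2.38 ± 0.30 and 1.65 ± 0.28. The call ended without SHR replicate 3 (mean 0.16, adjusted p = 0.0694) and with the filter at the 50th percentile (0.23, adjusted p = 0.133).

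The calcium handling and ion channel list was higher in SHR by a mean of 0.25 over 34 genes (adjusted p = 0.0333, and adjusted p = 0.664 with an estimated correlation). Trpc4 was its only member that passed over all probe sets, and 2 were higher when adjusted over the list alone. Cacna1d, a voltage-gated calcium channel, lay at 3.60 ± 0.33 in SHR and 2.53 ± 0.34 in WKY, and Ano1, a calcium-activated chloride channel, at 7.95 ± 0.24 and 6.78 ± 0.67. Kcnk3, a background potassium channel, lay on the other side, at 4.87 ± 0.19 and 5.46 ± 0.26. The call ended without SHR replicate 3 (mean 0.18, adjusted p = 0.366), without WKY replicate 3 (0.16, adjusted p = 0.174), with the filter at the 50th percentile (0.28, adjusted p = 0.0655), with a further quantile normalization (0.22, adjusted p = 0.0599) and with array weights (0.17, adjusted p = 0.118). It also ended with the white adipocyte mean as a covariate, a setting chosen after seeing the data (0.22, adjusted p = 0.161).

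The mitochondrial respiration list was lower in SHR by a mean of 0.22, with 25 of its 27 genes below 0 (adjusted p = 0.000616, and adjusted p = 0.664 with an estimated correlation). No member passed in limma over all probe sets or when adjusted over the list alone, and 0 had an unadjusted p under 0.05. The subunits Sdhd, Uqcrc1, Cox4i1 and Ndufv1 differed by -0.33, -0.43, -0.38 and -0.45, and without WKY replicate 1 Uqcrc1 and Ndufv1 by -0.25 and -0.18. Without SHR replicate 3 the mean was -0.12 (adjusted p = 0.0694) and without WKY replicate 1 it was -0.06 (adjusted p = 0.259). With the white adipocyte mean as a covariate, chosen after seeing the data, the list still passed (-0.14, adjusted p = 0.0343), as it did without both SHR replicate 1 and WKY replicate 3, chosen likewise (-0.34, adjusted p = 0.000369). Its mean level was 6.96, 6.99 and 6.68 on SHR replicates 1 to 3 and 7.43, 6.92 and 6.95 on WKY replicates 1 to 3. Skeletal and cardiac muscle markers lay at 2.45, 2.51 and 2.55 and at 3.12, 2.52 and 2.89 on these arrays, and brown adipocyte markers were highest on WKY replicate 1, at 5.63 against 3.70 to 4.67 on the others. The fatty acid and lipid metabolism list had a mean difference of -0.34 over 26 genes (adjusted p = 0.0359, and adjusted p = 0.716 with an estimated correlation), with 0 members passing in limma over all probe sets or adjusted over the list alone and 1 at an unadjusted p under 0.05. Mgll and Srebf1, a lipase and a regulator of lipid synthesis, differed by -0.35 and -0.53 (Srebf1 by -0.28 without WKY replicate 1), while Ppargc1a, a coactivator of mitochondrial genes, lay at 5.02 ± 0.37 in SHR and 4.19 ± 0.09 in WKY. The adjusted p of the lipid list was 0.0681 without SHR replicate 2 (mean -0.36) and 0.407 without SHR replicate 3 (mean -0.05), and without WKY replicate 1 its mean turned to 0.05 (adjusted p = 0.915). With the white adipocyte mean as a covariate, chosen after seeing the data, it was -0.07 (adjusted p = 0.335). It was farther from 0 without SHR replicate 1 (-0.62, adjusted p = 0.00101), without WKY replicate 3 (-0.61, adjusted p = 0.00140), without both (-0.88, adjusted p = 0.000197) and with array weights (-0.59, adjusted p = 0.000720). The aortae had been cleaned of adhering fat, per the labels. The mean level of white adipocyte markers was 7.58, 5.83 and 4.20 on SHR replicates 1 to 3 and 7.49, 6.00 and 6.07 on WKY replicates 1 to 3.

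The immediate early and heat shock list was lower in SHR by a mean of 0.32, with 17 of 24 genes below 0 (adjusted p = 0.0191, and adjusted p = 0.664 with an estimated correlation). No member passed in limma over all probe sets or when adjusted over the list alone, and 5 genes of 24 had an unadjusted p under 0.05, 1 higher and 4 lower. The transcription factor gene Jun lay at 6.84 ± 0.29 in SHR and 7.71 ± 0.35 in WKY, Fosb at 3.45 ± 0.14 and 4.10 ± 0.42, and Nr4a1, a nuclear receptor, at 5.23 ± 0.59 and 6.61 ± 1.05 (a difference of -0.83 without WKY replicate 2), whereas Egr2 differed by 0.51 ± 0.16 (SE). A dimmer probe set of Jun gave -0.72 beside the -0.86 of the brighter. The call ended without SHR replicate 2 (mean -0.25, adjusted p = 0.0681), without SHR replicate 3 (-0.31, adjusted p = 0.0556) and without WKY replicate 2 (-0.19, adjusted p = 0.205).

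The list of genes reported in earlier genetic work on SHR had a mean difference of -0.25 over 12 measured genes (adjusted p = 0.0191, and adjusted p = 0.664 with an estimated correlation). Over all probe sets 0 members passed in limma, 4 had an unadjusted p under 0.05, and when adjusted over the list alone 1 was higher and 2 lower. Agtr1b differed by -1.14, Endog, a mitochondrial nuclease, by -0.72 and Spon1, a matrix protein, by -1.07 (-0.63 without SHR replicate 3), while Ephx2, the soluble epoxide hydrolase, lay at 2.91 ± 0.69 in SHR and 1.74 ± 0.36 in WKY. The other 8 measured genes had an unadjusted p above 0.05. Without SHR replicate 3 the mean was -0.14 (adjusted p = 0.112) and without WKY replicate 1 it was -0.16 (adjusted p = 0.121). With the white adipocyte mean as a covariate, chosen after seeing the data, the mean was -0.16 and the adjusted p 0.230. It was farther from 0 with the filter at the 50th percentile (-0.40, adjusted p = 0.00250) and without both SHR replicate 1 and WKY replicate 3 (-0.40, adjusted p = 0.00253).

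The other programme lists did not pass. Those of the vessel wall were contractile smooth muscle (mean difference -0.04, adjusted p = 0.496), fibrillar matrix and elastic fibres (0.15, adjusted p = 0.0735), basement membrane (0.14, adjusted p = 0.0829), matrix proteases and inhibitors (0.06, adjusted p = 0.496) and growth factor and TGF-beta signalling (0.13, adjusted p = 0.0686). None of their members passed over all probe sets, and when adjusted over the list alone 3 fibrillar matrix, 2 protease and 2 growth factor genes were higher in SHR. Col8a1, a short-chain collagen, lay at 6.93 ± 0.41 in SHR and 5.20 ± 0.18 in WKY (limma adjusted p = 0.0848), and the matrix proteins Postn, Fn1 and Spp1 differed by 1.46, 0.92 and 0.58. Timp1, an inhibitor of metalloproteinases, differed by 1.03 and the protease Ctsk by 1.17. The growth factor genes Tgfb1 and Pdgfa and the receptor gene Tgfbr1 differed by 0.74, 1.03 and 0.90. Of the smooth muscle genes, Lmod1 lay at 8.39 ± 0.16 in SHR and 8.66 ± 0.30 in WKY, and Tpm2 at 9.54 ± 0.24 and 9.75 ± 0.09. Lmod1 differed by -0.18 without SHR replicate 1 and -0.11 without WKY replicate 3, and Tpm2 by -0.07 without SHR replicate 1. Without SHR replicate 2 the fibrillar matrix (0.18) and basement membrane (0.18) lists passed, each with an adjusted p of 0.0488. Without SHR replicate 3 the basement membrane mean was 0.09 (adjusted p = 0.366). With no filter on dim probe sets the fibrillar matrix (0.15, adjusted p = 0.0462) and growth factor (0.13, adjusted p = 0.0423) lists passed. Without both SHR replicate 1 and WKY replicate 3, a setting chosen after seeing the data, the means of these lists were 0.04 (adjusted p = 0.186) and -0.12 (adjusted p = 0.904), without SHR replicate 1 alone 0.10 (adjusted p = 0.185) and 0.02 (adjusted p = 0.674), and without WKY replicate 3 alone 0.09 (adjusted p = 0.0793) and -0.0050 (adjusted p = 0.413). The growth factor list also passed without SHR replicate 2 (0.18, adjusted p = 0.0337), WKY replicate 1 (0.21, adjusted p = 0.0479) or WKY replicate 2 (0.19, adjusted p = 0.0381). Leaving out single arrays, the contractile mean ranged from -0.12 without SHR replicate 3 (adjusted p = 0.0694) to 0.05 without SHR replicate 1 (0.629), and the protease mean from -0.01 without SHR replicate 1 (0.965) to 0.11 without SHR replicate 3 (0.366).

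Among lists of vasoactive systems, renin-angiotensin (mean -0.22, adjusted p = 0.470), nitric oxide and cGMP (-0.03, adjusted p = 0.460), endothelin and prostanoids (0.01, adjusted p = 0.886) and the amine and vasopressin receptors (0.08, adjusted p = 0.878) did not pass. When adjusted over the list alone 1 renin-angiotensin gene, Agtr1b, was lower, and 1 gene each of the nitric oxide and receptor lists, Ddah1 and Htr1b, was higher. Agt, the precursor of angiotensin, lay at 3.53 ± 0.86 in SHR and 4.76 ± 0.60 in WKY. Ddah1, which breaks down an inhibitor of nitric oxide synthase, lay at 6.90 ± 0.22 and 5.73 ± 0.09 (limma adjusted p = 0.0974), and the serotonin receptor Htr1b at 6.84 ± 0.55 and 5.19 ± 0.43 (limma adjusted p = 0.308). Ptgs2, an enzyme of prostaglandin synthesis, lay at 7.94 ± 0.86 and 9.19 ± 0.75. For the renin-angiotensin list the median, 0.08, had the opposite sign of the mean and the test, and for the receptor list the mean was above 0 while the median and the test pointed down. Without both SHR replicate 1 and WKY replicate 3, a setting chosen after seeing the data, the renin-angiotensin list passed as lower in SHR (-0.62, adjusted p = 0.0215). Its mean was -0.45 without SHR replicate 1 alone (adjusted p = 0.0678), -0.39 without WKY replicate 3 alone (0.103), -0.04 without SHR replicate 3 (0.747), -0.07 without WKY replicate 1 (0.915) and -0.06 with the adipocyte covariate (0.459). The endothelin and prostanoid mean ranged from -0.07 without SHR replicate 1 (0.833) to 0.06 without SHR replicate 3 (0.819). That of nitric oxide ranged from -0.07 without WKY replicate 3 (0.306) to -0.00092 without WKY replicate 2 (0.680). The receptor mean ranged from 0.02 without SHR replicate 1 (0.674) to 0.14 without SHR replicate 2 (0.651).

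The lists of inflammatory cytokines and adhesion (mean 0.16, adjusted p = 0.0501), oxidant and antioxidant genes (0.07, adjusted p = 0.513), interferon response (0.04, adjusted p = 0.789) and the circadian clock (-0.06, adjusted p = 0.496) did not pass either. None of their members passed over all probe sets, and when adjusted over the list alone Gstm2 was lower and Ifit1 higher. The chemokine Ccl2 lay at 5.11 ± 0.55 in SHR and 3.93 ± 0.15 in WKY, and the adhesion molecules Icam1 and Vcam1 differed by 0.55 and 1.10, the second by 0.73 without WKY replicate 3. Ifit1, an interferon-induced gene, lay at 3.16 ± 0.70 and 1.24 ± 0.18, and Gstm2, a glutathione transferase, at 6.79 ± 0.10 and 7.64 ± 0.08. Per1 and Per3 of the clock differed by -0.68 and -0.63, and without WKY replicate 1 by -1.08 and -0.98. Without WKY replicate 3 the difference of Per3 was -0.29. A mean over the clock list cannot show members that move in opposite directions. The clock gene Bmal1, named after its values were seen, lay at 6.15, 4.55 and 5.13 on SHR replicates 1 to 3. On WKY replicates 1 to 3 it lay at 6.44, 3.91 and 3.01. Per3 lay at 3.48, 3.81 and 4.04 and at 3.70, 4.42 and 5.09 on these arrays. The cytokine list passed without SHR replicate 2 (0.20, adjusted p = 0.0309) or SHR replicate 3 (0.29, adjusted p = 0.00395), with no filter on dim probe sets (0.15, adjusted p = 0.0300), with a further quantile normalization (0.17, adjusted p = 0.0285) and with the mean of a gene's probe sets (0.16, adjusted p = 0.0496). Of the settings chosen after seeing the data, the adipocyte covariate made it pass (0.26, adjusted p = 0.00972), and without both SHR replicate 1 and WKY replicate 3 its mean was -0.06 (adjusted p = 0.950). With that covariate the oxidant list passed as higher (0.18, adjusted p = 0.0343), and without those 2 arrays the oxidant (-0.22, adjusted p = 0.0169) and interferon (-0.26, adjusted p = 0.00322) lists passed as lower. Without SHR replicate 1 alone the cytokine mean was -0.01 (adjusted p = 0.976) and without WKY replicate 3 alone 0.11 (0.0793). Leaving out single arrays, the oxidant mean ranged from -0.08 without WKY replicate 3 to 0.19 without SHR replicate 3, and the interferon mean from -0.12 without SHR replicate 1 to 0.18 without SHR replicate 3, with no pass, and the clock mean from -0.14 without WKY replicate 1 (0.0990) to 0.04 without WKY replicate 2 (0.929). In the interferon list the mean was above 0 while its median, -0.08, and the test were below.

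Of the 11 cell type marker lists, 2 passed camera with a preset correlation, both lower in SHR. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05) and by fry 0 (1 at an unadjusted p under 0.05). Skeletal and cardiac muscle markers had a mean difference of -0.34, with 12 of 13 genes below 0 (adjusted p = 0.00141, and adjusted p = 0.578 with an estimated correlation). Acta1, Tnni2 and Ckm differed by -0.51, -0.38 and -0.70, the last by -0.32 without WKY replicate 1. Without WKY replicate 1 the mean was -0.20 and the adjusted p 0.0669, and without both SHR replicate 1 and WKY replicate 3, a setting chosen after seeing the data, they were -0.29 and 0.177. With the filter at the 50th percentile the mean was -0.58 (adjusted p = 0.000169). White adipocyte markers had a mean difference of -0.65, with 13 of 14 genes below 0 (adjusted p = 0.0437, and adjusted p = 0.774 with an estimated correlation), and Dgat2 and Plin1, of triglyceride synthesis and the lipid droplet, differed by -1.33 and -1.02, by -0.48 and -0.01 without SHR replicate 3, by -2.05 and -1.95 without SHR replicate 1 and by -0.73 and -0.54 without WKY replicate 1. No member of either list passed in limma, over all probe sets or adjusted over the list alone, and 2 muscle and 0 adipocyte genes had an unadjusted p under 0.05. The adipocyte call ended without SHR replicate 2 (mean -0.63, adjusted p = 0.0986) and without WKY replicate 1 (-0.17, adjusted p = 0.558), and without SHR replicate 3 the mean turned to 0.19 (adjusted p = 0.655). It was farther from 0 without SHR replicate 1 (-1.51, adjusted p = 6.76e-10), without both SHR replicate 1 and WKY replicate 3 (-1.73, adjusted p = 5.21e-07) and with array weights (-0.99, adjusted p = 0.00171). The estimated correlation between genes was 0.930 in the adipocyte list and 0.372 in the muscle list, against the preset 0.01. The preset p-values of both lists are therefore too small. With all arrays the exact permutation p of the adipocyte list mean was 0.5.

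The remaining marker lists did not pass: endothelial cell (mean -0.35, adjusted p = 0.0680), erythroid cell (-0.58, adjusted p = 0.0778), nerve and Schwann cell (0.51, adjusted p = 0.0830), neutrophil and mast cell (-0.20, adjusted p = 0.0926), brown adipocyte (-0.52, adjusted p = 0.138), fibroblast and adventitia (-0.24, adjusted p = 0.227), B and plasma cell (0.12, adjusted p = 0.627), macrophage (-0.03, adjusted p = 0.848) and T and NK cell (0.03, adjusted p = 0.952). When adjusted over the list alone 2 brown adipocyte genes, Ppargc1a and Dio2, were higher and 0 others passed. The nerve list lay at 4.96 on SHR replicate 1 and between 2.88 and 3.15 on the other 5 arrays, and Th, the enzyme that begins catecholamine synthesis, at 3.01 ± 2.52 in SHR and 1.43 ± 0.28 in WKY, a difference of 0.12 without SHR replicate 1. The endothelial junction gene Cldn5 lay at 4.04 ± 0.77 and 5.03 ± 0.35 (a difference of -0.63 without SHR replicate 3), the adventitial fibroblast gene Pi16 at 5.68 ± 1.38 and 7.22 ± 0.27 (-0.83 without SHR replicate 3), and the haemoglobin gene Hba-a1 at 2.43 ± 1.44 and 4.20 ± 0.88. On the other side lay Flt1 of the endothelial list (0.55, and 0.26 without WKY replicate 3) and Fap of the fibroblast list (0.57). Below 0 were 10 of 13 endothelial and 9 of 13 fibroblast genes.

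Several of these marker lists passed under other settings, in camera at the preset correlation of 0.01. With all arrays the estimated correlation was 0.630 for the endothelial, 0.860 for the fibroblast, 0.887 for the macrophage and 0.583 for the nerve list. It was 0.295 for the brown adipocyte, -0.025 for the neutrophil and mast cell and -0.016 for the erythroid list. Where it exceeds the preset, the p-values here are too small. The endothelial list passed with all 6 arrays as lower in SHR with the filter at the 50th percentile (-0.35, adjusted p = 0.0292), a further quantile normalization (-0.38, adjusted p = 0.0375), median centring (-0.30, adjusted p = 0.0295) and array weights (-0.59, adjusted p = 0.00125). With array weights the fibroblast (-0.48, adjusted p = 0.00619) and neutrophil and mast cell (-0.30, adjusted p = 0.0384) lists passed too. Without SHR replicate 1 the endothelial (mean -0.75, adjusted p = 1.74e-07), fibroblast (-0.64, adjusted p = 1.95e-06), macrophage (-0.58, adjusted p = 3.88e-06), neutrophil and mast cell (-0.37, adjusted p = 0.00722) and erythroid (-0.79, adjusted p = 0.0258) lists passed as lower in SHR. Without SHR replicate 3 the macrophage list passed as higher (0.44, adjusted p = 0.0103), and so did the nerve list (0.84, adjusted p = 0.0102). The nerve list also passed without SHR replicate 2 (0.87, adjusted p = 0.00158) or WKY replicate 3 (0.55, adjusted p = 0.0493), all with SHR replicate 1 in the fit, while without that array its mean was -0.17 (adjusted p = 0.325). Others that passed were the endothelial list without WKY replicate 3 (-0.49, adjusted p = 0.0453) and the brown adipocyte list without WKY replicate 2 (-0.84, adjusted p = 0.00904). Without both SHR replicate 1 and WKY replicate 3, a setting chosen after seeing the data, the endothelial (-0.89), fibroblast (-0.80), macrophage (-0.66) and neutrophil and mast cell (-0.44) lists passed as lower, with adjusted p of 3.84e-07, 3.84e-07, 0.000141 and 0.0131, and the nerve mean was -0.13 (adjusted p = 0.896). With the adipocyte covariate, chosen likewise, the macrophage (0.35, adjusted p = 0.000337) and nerve (0.83, adjusted p = 0.00271) lists passed as higher.

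The same marker lists came close to 0 or turned in other fits, in which they did not pass. Without SHR replicate 3 the endothelial mean was -0.06 (adjusted p = 0.578), the fibroblast mean 0.10 (0.466), the neutrophil and mast cell mean -0.07 (0.466) and the brown adipocyte mean -0.24 (0.466). Without WKY replicate 1 they were -0.17 (0.558), -0.12 (0.837), -0.09 (0.558) and -0.08 (0.881), and the macrophage mean was 0.21 (0.558). With the adipocyte covariate the endothelial, fibroblast, neutrophil and mast cell and brown adipocyte means were -0.09, 0.02, -0.07 and -0.25, with adjusted p of 0.264, 0.864, 0.394 and 0.394. The erythroid mean ranged from -0.79 without SHR replicate 1 to -0.41 without WKY replicate 2 (0.246), the B and plasma cell mean from -0.11 without SHR replicate 1 (0.387) to 0.24 without SHR replicate 2 (0.206), and the T and NK cell mean from -0.07 without SHR replicate 1 (0.536) to 0.11 without SHR replicate 3 (0.602).

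**Figure D3:**
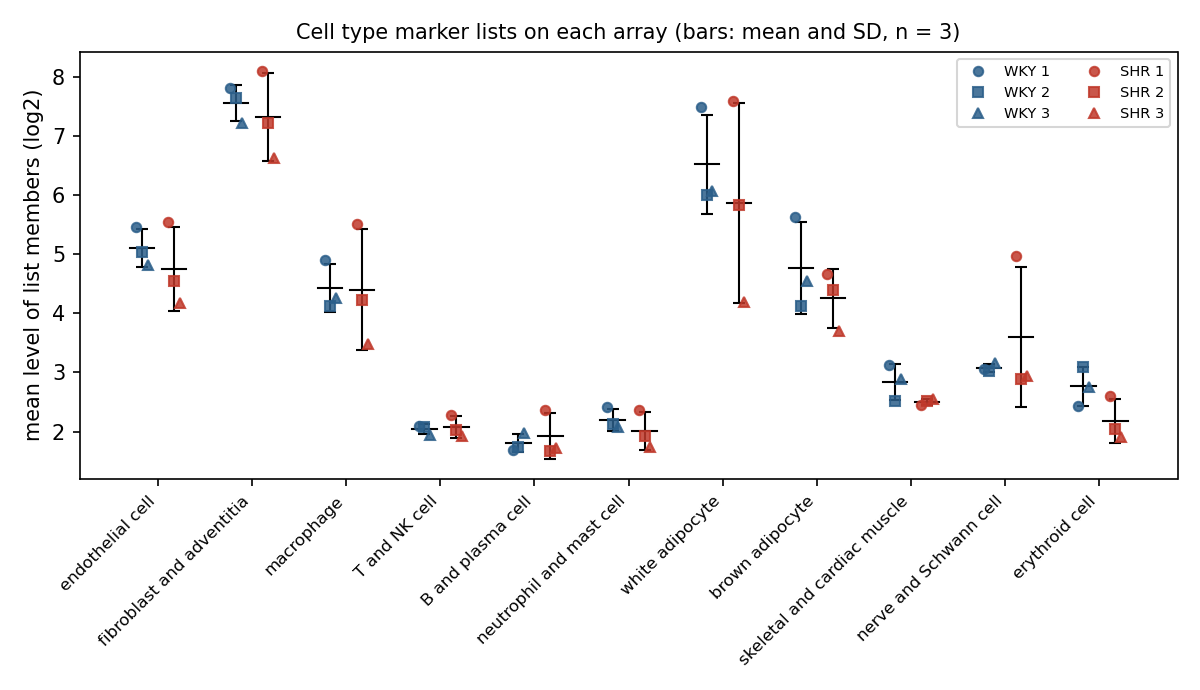
The mean level (log2) of the members of each of the 11 cell type marker lists is shown on each array, blue for WKY and red for SHR, with the replicate given by the shape of the point and bars for the mean and SD (n = 3). White adipocyte markers range from 4.20 on SHR replicate 3 to 7.58 on SHR replicate 1, and nerve markers stand at 4.96 on SHR replicate 1.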

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

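Of the alternatives, leaving out both SHR replicate 1 and WKY replicate 3, the adipocyte covariate and counting identical probe sets once were chosen after seeing the data. All 13 passing genes kept their direction in each of the 17 alternatives run for them, and Il1rl2 and Olr1 passed in all 17. Long non-coding RNAs stayed at 0 passing in every alternative run, the unadjusted thresholds with a fold limit included. The replicate block left 3 probe sets, 3 higher and 0 lower, for 3 genes, all 3 coding, and gave 4 marker lists, with the endothelial (adjusted p = 0.00261) and brown adipocyte (0.0453) lists passing there, and the cytokine list as well (0.0475). Same-numbered arrays deviated from their group means with r of 0.354, -0.0786 and 0.228 across probe sets, which are not independent replicates, which does not show that the numbers pair the arrays, and a shared day or batch is not excluded. SHR replicates 1 and 3 correlated best with their own number, and SHR replicate 2 with WKY replicate 3 (0.166).

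Array weights gave 65 probe sets, 48 higher and 17 lower (57 genes, 55 coding), and 5 marker lists. An unadjusted p under 0.05 with 1.5-fold gave 578 probe sets, 334 higher and 244 lower (424 genes, 415 coding), and with 2-fold 158, 108 higher and 50 lower (115 genes, 112 coding). Without SHR replicate 1 and WKY replicate 3 together there were 115 probe sets, 39 higher and 76 lower (71 genes, 70 coding), and 5 marker lists. Without the filter, and with median centring, 1 probe set was lower. The estimated correlation and fry each left 0 programme and 0 marker lists. Leaving out each array in turn gave 2 to 5 probe sets, 2 to 5 higher and 0 lower, 2 to 5 genes, 2 to 5 coding genes, 1 to 8 programme lists and 0 to 7 marker lists, from fewer arrays in each fit. The cause of the other changes was not tested.

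Of 535 list values under the alternatives, 6 turned sign with a call on either side. Leaving out single arrays, the macrophage list ranged from -0.579 to 0.435, highest without SHR replicate 3, white adipocyte from -1.51 to 0.185, highest without SHR replicate 3, and fatty acid and lipid metabolism from -0.619 to 0.0509, highest without WKY replicate 1. With the adipocyte covariate the macrophage list lay at 0.350. Without SHR replicate 1 and WKY replicate 3 the oxidant list lay at -0.216 and the interferon list at -0.261. The skeletal and cardiac muscle call was also lost there. Among the others 39 list values gained a call and 39 lost one, and 40 changed sign with no call on either side. Of 2353 gene values 15 gained a call, 83 lost one and 19 changed sign uncalled. The adipocyte list has no value with its own mean as covariate. The planned test of coding neighbours of changed non-coding RNAs was not run. In arrays the signal over background sets the limit for dim probe sets, and no detection call was used here.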

Other observations

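The tests of adipose tissue, of WKY replicate 3, of neighbouring genes and of strain variants, and the splits for probe sets and genes, were chosen after the results were seen, as were the correlations with adipocyte markers. The mean level of the white adipocyte markers was set against 29 other list means over the 6 arrays. Pearson's r was 0.965 for endothelial cells, 0.946 for fibroblasts, 0.953 for macrophages and 0.968 for neutrophils and mast cells, with exact permutation p of 0.00417, 0.00556, 0.00417 and 0.00556 and an adjusted p of 0.0403 each. Spearman's rho was 0.943, 0.943, 0.943 and 0.886, with exact permutation p of 0.0167, 0.0167, 0.0167 and 0.0333, and none of the 29 passed after adjustment (0.121, 0.121, 0.121 and 0.138). Without the 2 arrays farthest from the median r was 0.900, 0.762, 0.980 and 0.948. None of the other lists passed by either coefficient. For the renin-angiotensin list r was 0.919 (exact permutation p = 0.0111, adjusted p = 0.0644), rho 0.771 (exact permutation p = 0.103, adjusted p = 0.271) and r without those 2 arrays 0.829. For contractile smooth muscle, the lowest of the 29, r was -0.887 (exact permutation p = 0.0292, adjusted p = 0.116), rho -0.771 (exact permutation p = 0.103, adjusted p = 0.271) and r without those 2 arrays -0.753. For the list from earlier SHR genetics r was 0.908 (exact permutation p = 0.0208, adjusted p = 0.101), rho 0.943 (exact permutation p = 0.0167, adjusted p = 0.121) and r without those 2 arrays 0.979. The strains did not separate in the adipocyte mean itself (exact permutation p = 0.5, two-sided, where 3 against 3 cannot go below 0.1).

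WKY replicate 3 held high levels of pancreatic enzyme genes, named here after their values were seen: Ctrb1 lay at 6.18 there and between 2.98 and 5.18 on the other arrays, and Cela1 at 4.67 and between 2.37 and 3.16. In the added list of 19 measured pancreatic acinar genes the median excess of this array over the mean of the other 5 was 0.49, and 13 members were highest on it. Random lists of the same size and mean level, drawn after this was seen, had a median excess of 0.13 on this array and stayed at or below 0.29 in all but the top 2.5% of 10000 draws. SHR replicate 1 came next for Ctrb1 and Cela1, at 5.18 and 3.16. Amy2a3, also named after its values were seen, lay at 5.34 there and 5.63 on WKY replicate 3. In the added list the median excess of SHR replicate 1 was 0.065, and 2 members were highest on it. Jchain, of antibody-secreting cells, lay at 5.76 on SHR replicate 1 and between 1.56 and 2.59 on the others.

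The fatty acid and mitochondrial lists were called lower in SHR by camera at the preset correlation, and not at an estimated one (adjusted p = 0.716 and 0.664). Without WKY replicate 1 the mean of the lipid list turned to 0.05. A candidate explanation for both is a different amount of adipose tissue on each aorta. Over the 6 arrays Pearson's r with the adipocyte mean was 0.873 for the lipid list (exact permutation p = 0.0319, adjusted p = 0.116). For the mitochondrial list r was 0.765 (exact permutation p = 0.110, adjusted p = 0.227). Spearman's rho was 0.771 and 0.543, and r without the 2 arrays farthest from the median was 0.945 and 0.970. With the adipocyte mean as covariate the difference of the lipid list, without the 4 genes shared with fat cell lists, went from -0.32 ± 0.48 (SE) to -0.0738 ± 0.30, and that of the mitochondrial list from -0.22 ± 0.19 to -0.14 ± 0.15, with which camera still called the mitochondrial list (adjusted p = 0.0343) and not the lipid list (0.335). Both lay within 2 SE of 0 before the correction, a rule added after a first look at the values, so the test of the list means decides nothing, and adipose tissue and strain cannot be told apart for these lists. Leaving out WKY replicate 3, the array of narrow spread, gave -0.61 for the lipid list, but it already had the lowest WKY mean of the list, 5.82 against 7.14 and 6.08, which fixed this outcome, so the test decides nothing about its narrow spread. A biological difference between the strains also remains open and untested.

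Nerve transcripts were high on SHR replicate 1, where Snap25, of synaptic vesicle release, lay at 7.61 against 1.37 to 2.29 on the other arrays, Th at 5.92 against 1.13 to 1.68 and Npy, a neuropeptide, at 7.68 against 3.16 to 4.87, genes that include some named after their values were seen. Sympathetic ganglion tissue on that aorta is a candidate source. In a separate list of 24 measured sympathetic neuron genes the median excess of this array was 0.589 and 16 members (66.7%) were highest on it, below the bounds of 1 and 75% set beforehand for this source and above the 0.3 set against it, so it stays open. A shift of dim genes by normalization is argued against, because random lists of the same size and mean level stayed at or below 0.0583 in all but the top 2.5% of 10000 draws. The pattern lies in 1 array, so no biological explanation by strain was tested.

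Among the 100 genes of smallest p, 4 pairs were next to each other in the gene order of assembly GRCr8 and differed in the same direction: Setd4 with Cbr1, Cbr1 with Cbr3, Trpc4 with Postn and Il1r1 with Il1rl2, of which Setd4, Cbr3 and Il1r1 are outside the naming rule. Chance placement gave 0.387 pairs on average, and the share of random draws with as many was 0.00060. This test was chosen after the results were seen, and its draws place genes independently. The pairs with Setd4 and with Cbr3 both rest on Cbr1, whose other probe sets did not move with it. The share is therefore low but does not by itself exclude chance placement. Shared sequence within gene families may account for part. Without pairs that share a symbol stem 2 remained against 0.359 by chance, a share of 0.0507 that lies at the threshold. Chance placement of these 2, Setd4 with Cbr1 and Trpc4 with Postn, is therefore not excluded, and a shared stem does not explain them. With 50, 200 and 500 genes the shares without shared stems were 0.097, 0.0486 and 0.0968. Strain variants under the probes, and inherited differences in regulation between the strains, stay open, because only 1 passing gene, Cbr1, had other tested probe sets, and in that 1 they did not move with it.

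With 10 splits of the 6 arrays no share under 0.05 can be reached. The real split gave 15 probe sets and 13 coding genes and the highest other split 3 of each. Only the real split among the 10 reached these counts. For programme lists the real split gave 6 and the highest other 8, with 4 splits as large, the real one included. For marker lists the values were 2 and 8, with all 10 as large, the real one included. The split of SHR replicate 1 with WKY replicates 1 and 2 from the other arrays had 2289 probe sets at an unadjusted p under 0.05, against 1202 in the real one. It was picked as the highest after all splits had been computed, and 3 probe sets passed in it. A structure of the samples other than strain was not tested.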
